A study of Mus musculus with 19 samples.

How the data were processed

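Gene expression was measured by RNA-seq in sorted pancreatic epithelial cells of 19 mice: Normal (n = 4), Injury (n = 5), Kras* (n = 3), Kras*+Injury (n = 4) and PDAC (n = 3). The deposited table holds read counts per gene for 53465 mouse genes, made by the authors with Trimmomatic 0.36, STAR 2.5.3a, featureCounts 1.6.3 and DESeq2 1.20.0 on builds GRCm38 and mm10, per the submitters' processing notes, which state neither the annotation release nor how reads with several alignments or antisense reads were counted. Counts of paralogs such as the Reg family genes can therefore share reads. The deposited counts were whole numbers with totals that differ between libraries, as raw counts do. Of the gene IDs, 53274 are in GENCODE M21 and 51335 have the same start and end there. Injury and Kras*+Injury columns carry other group names in the table than in the series design and were assigned through the sample titles.

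The counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 15145 genes, libraries were scaled by trimmed mean of M values (TMM), and a robust quasi-likelihood fit with 1 coefficient per group over all 19 libraries gave 8 contrasts. Genes with a Benjamini-Hochberg adjusted p under 0.05 (two-sided) were called. Levels are given as CPM on the effective library sizes with the mean and SD of the libraries, and log2 fold changes with their SE from the fit. In comparisons of 2 groups, for a gene with 1 to 3 counts over a group the ratio is given with a 95% counting interval, which covers counting error only. The 12 rows of ribosomal RNA-like reads stayed in the totals. A count of 3 was used as the floor of detection.

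The gene lists, 22 with 469 genes of which 467 were found, were acinar secretory genes, acinar transcription factors, ductal and metaplasia genes, gastric and precursor lesion genes, Reg family genes, AP-1 transcription factors, dissociation stress genes, cytokines with alarmins and chemokines, RAS-MAPK output genes, EMT and invasion genes, proliferation genes, p53 target genes, unfolded protein response genes, interferon response genes, cholesterol synthesis genes, glycolysis and hypoxia genes, and markers of immune, fibroblast and stellate, endothelial, endocrine and erythroid cells and of sex. Each list with at least 4 tested members was tested in each contrast with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 176 tests. The same test with an estimated correlation and fry, which asks only whether the members move 1 way on balance, were run beside it.

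Comparisons, tests, gene lists, the rule for naming genes and the first set of other settings were fixed before the data were examined. Named by that rule are, per contrast, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups compared (no such condition for the interaction), without predicted genes and immune receptor segments. Up to 4 called members of each list with a mean log2 CPM of at least 1, uncalled members with their value, and Kras, Trp53, Il33, Ptf1a, Krt19, Sox9, Cdkn2a, Cdkn1a, Myc and Mki67 may be named too, and the text names a part of these. Mcpt1 and Mcpt2 were chosen after their values were seen.

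Log2 fold changes of PDAC against Normal were compared with those of other contrasts across genes by Pearson and Spearman coefficients and covariance. Unchanged groups against the same Normal libraries were simulated 20 times, and the Normal libraries were divided between the contrasts in 6 ways. Each gene was simulated independently, so the simulated values carry none of the correlation between genes. The test was checked on simulated data with 200 changed genes: of genes changed 4-fold it called 46.3% for Injury against Normal, 58.2% for Kras*+Injury against Kras* and 26.9% for the interaction, with 3 false calls in each. Of genes changed 2-fold it called 2.99%, 5.97% and 4.48% in the same order.

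That first set held DESeq2's median-of-ratios factors and upper-quartile factors in edgeR, TMM without acinar secretory genes, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma's voom with sample quality weights, fits of only the groups compared or without PDAC, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were totals without acinar secretory and ribosomal RNA-like rows, a per-library correction for transcript length, a fibroblast marker covariate, a filter of 5 CPM in 3 libraries, and fits without Normal replicates 1 and 4, without Kras* replicate 2 and Kras*+Injury replicate 1, or without Kras*+Injury replicate 4 and PDAC. The scaling moved the median log2 fold change of all genes by over 0.1 in some contrasts: it was -0.14 instead of -0.01 (Kras*+Injury against Kras*), 0.24 instead of 0.04 (PDAC against Kras*+Injury) and 0.16 instead of 0.26 (Kras*+Injury against Normal) with median-of-ratios factors, and 0.07 instead of 0.26 (Kras*+Injury against Normal), -0.12 instead of 0 (Kras*+Injury against Injury) and 0.37 instead of 0.48 (PDAC against Normal) with upper-quartile factors. No library was left out of the main comparisons.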

Results

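The data are RNA-seq read counts of pancreatic epithelial cells from 19 mice in 5 groups. The mice expressed Cre recombinase in the pancreas and carried a Cre-dependent mKate2 reporter. Living mKate2-positive cells without CD45, a surface marker of leukocytes, were sorted from dissociated tissue. Normal (n = 4) and Injury (n = 5) mice had wild-type Kras, the gene of a small GTPase upstream of the MAPK cascade. Kras* (n = 3) and Kras*+Injury (n = 4) mice carried a mutant Kras allele switched on by Cre. Injury was made with caerulein, a secretagogue that causes acute pancreatitis, given to male mice 5 weeks old at 80 µg/kg in 8 hourly injections on each of 2 days. The Normal and Kras* mice received vehicle, and cells of these groups were collected on day 2. PDAC (n = 3) denotes cells of pancreatic ductal adenocarcinoma from untreated mice with the mutant Kras allele and a floxed copy of Trp53, the gene of the tumour suppressor p53. The replicates were independent mice according to the series design.

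The libraries held between 6979576 counts (Injury replicate 5) and 42334128 counts (Kras*+Injury replicate 4). Ribosomal RNA-like reads took 2.64% (Kras*+Injury replicate 4) to 80.0% (Injury replicate 2) of them. The acinar secretory genes, which encode digestive enzymes and their cofactors, took 24.8% ± 4.48 (SD, n = 4) of the counts in Normal and 10.4% ± 7.43 (n = 5) in Injury libraries. Their share was 6.51% ± 3.14 (n = 3) in Kras*, 3.31% ± 4.38 (n = 4) in Kras*+Injury and 0.235% ± 0.33 (n = 3) in PDAC libraries. Without Kras*+Injury replicate 4 (9.87%) the mean of that group was 1.13% ± 0.258 (n = 3). Without PDAC replicate 3 (0.615%) the PDAC mean was 0.0454% ± 0.0288 (n = 2). Counts left for all other genes came to 678692 to 1310411 per Normal library, 1331888 to 3157316 per Injury library, 2881664 to 5818706 per Kras* library, 4050378 to 37038042 per Kras*+Injury library and 7673928 to 9789671 per PDAC library. A count of 3 corresponded to 2.4 CPM (the usual unit of counts scaled by effective library size) in Normal replicate 4 and to 0.022 CPM in Kras*+Injury replicate 4, so genes of low level were measured least precisely in the Normal libraries. These floors cover counting error only. Kras*+Injury replicate 4 is also described with a project letter that no other library has, and as a batch of 1 library it allows no value within the batch.

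**Figure D1:**
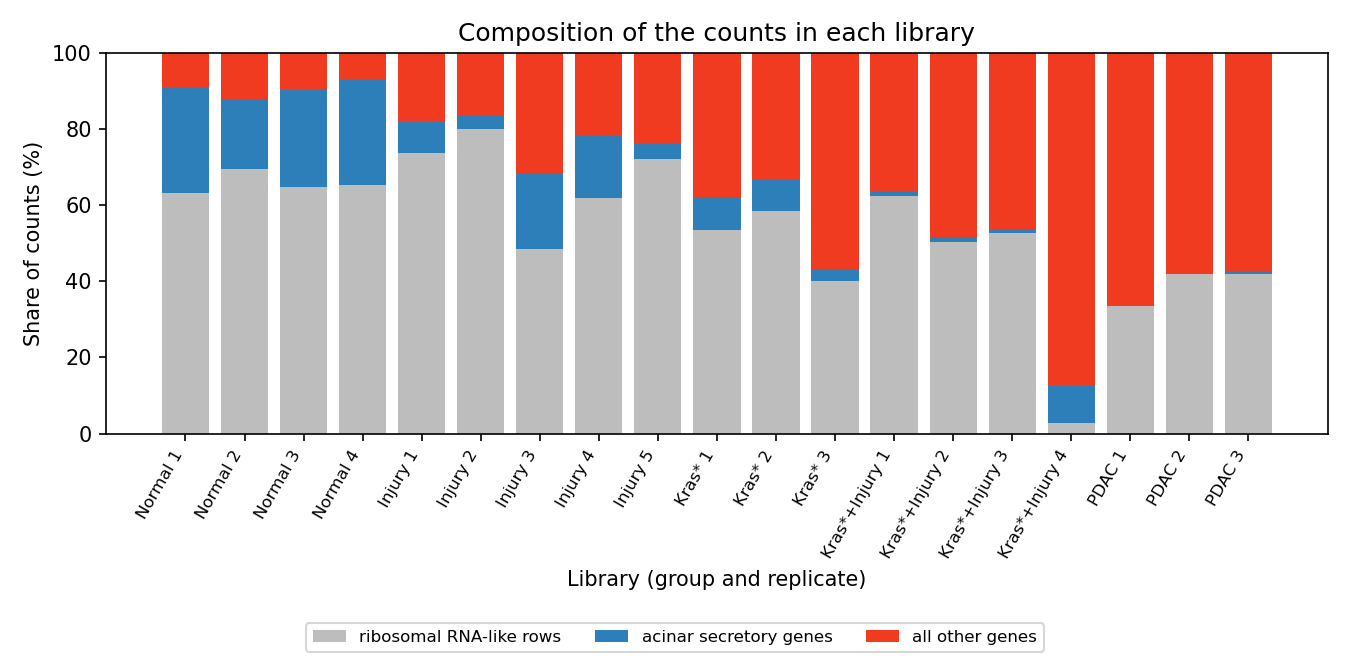
Share of the counts of each library (y axis, percent) taken by rows of ribosomal RNA-like reads, by the acinar secretory genes and by all other genes, for the 19 libraries on the x axis. The ribosomal RNA-like share falls between 2.64% and 80.0%, and the acinar secretory share is 18.3% or more in the Normal libraries and 0.615% or less in the PDAC libraries.

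Kras (chromosome 6, 145216699 to 145250239, mm10) and Trp53 (chromosome 11, 69580359 to 69591873) are the engineered genes. Kras was at 6.86, 17.1, 8.21 and 4.87 CPM in Normal replicates 1 to 4 and at 14.2, 21, 12.6, 12.7 and 23.3 CPM in Injury replicates 1 to 5. It was at 25.6, 25.8 and 28.1 CPM in Kras* replicates 1 to 3, at 22.2, 27.8, 23.5 and 30.9 CPM in Kras*+Injury replicates 1 to 4, and at 48.0, 108 and 47.2 CPM in PDAC replicates 1 to 3. Trp53 was at 1.37, 3.92, 7.80 and 10.6 CPM in the Normal replicates and at 25.8, 32.1, 33.8, 36.5 and 35.1 CPM in the Injury replicates. Its level was 32.4, 25.0 and 29.8 CPM in the Kras* replicates, 50.2, 32.5, 33.8 and 28.9 CPM in the Kras*+Injury replicates, and 20.4, 3.52 and 4.29 CPM in the PDAC replicates. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Trp53 was lower in PDAC than in Kras*+Injury libraries (log2 fold change -1.95 ± 0.48 SE, adjusted p = 0.00446) and did not pass the test between PDAC and Normal libraries (0.70 ± 0.53, adjusted p = 0.266), where it did pass after a correction for transcript length. Without PDAC replicate 1 these values were -3.31 and -0.61, the second still not passing. Kras did not pass between Injury and Normal libraries (0.78 ± 0.34, adjusted p = 0.105) except without Normal replicate 2 (1.29). The counts cover whole genes and do not tell the mutant from the wild-type Kras allele or the exons removed by Cre from the rest of Trp53.

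Injury in Kras wild-type cells was set against Normal to describe the response of the normal epithelium to pancreatitis. Digestive enzyme genes fell: Pnlip, the gene of pancreatic lipase (chromosome 19, 58670365 to 58681786), went from 113000 ± 59900 CPM (SD, n = 4) to 493 ± 367 CPM (n = 5), a log2 fold change of -7.84 ± 1.05. The phospholipase gene Pla2g1b changed by -6.30 ± 0.93 and the elastase gene Cela1 by -5.21 ± 0.92, and for these 3 genes every Injury library lay below every Normal library. Bhlha15, which encodes the transcription factor Mist1 of secretory cells, fell by 2.38 ± 0.52 and Xbp1, a regulator of secretory capacity, by 1.23 ± 0.29. Ptf1a, the main activator of acinar enzyme genes, stood at 12.8 ± 4.81 against 23.8 ± 12.8 CPM and did not pass (adjusted p = 0.286). The duct keratin genes Krt7 (log2 fold change 3.86 ± 0.50) and Krt19 (2.90 ± 0.39, 190 ± 49.1 against 25.8 ± 11 CPM) rose, as did Sox4, a transcription factor gene (4.38 ± 0.35), and Sprr1a, a gene of the epithelial cornified envelope (5.52 ± 0.65). Anxa10, a gene of the gastric epithelium, had 1 count over all Normal libraries, and its ratio was 212 with a 95% counting interval of 37.9 to 8370. Tff2, which encodes a trefoil peptide of mucous cells, fell from 2680 ± 2050 to 95.6 ± 53 CPM, with a log2 fold change of -4.81, and of -4.22 without Normal replicate 4. The single count of Anxa10 was in Normal replicate 2, and the other Normal libraries held none.

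Of the 28 acinar secretory genes 24 fell with Injury and none rose, and 26 fell when adjusted over the list alone (camera adjusted p = 3.02e-18, adjusted p = 0.226 with an estimated correlation). Of the 22 genes of the unfolded protein response, which keeps the folding of secreted proteins in balance, 15 fell and 1 rose (17 and 1 adjusted over the list alone), among them Edem1 (-2.08 ± 0.31) and Herpud1 (-2.07 ± 0.32), both of the degradation of misfolded proteins. The camera adjusted p was 6.14e-12 (adjusted p = 0.213 with an estimated correlation). Of 24 ductal and metaplasia genes 12 rose and none fell (15 adjusted over the list alone, camera adjusted p = 1.62e-08, adjusted p = 0.213 with an estimated correlation). Of 30 proliferation genes 17 rose, 22 adjusted over the list alone, such as the replication licensing gene Mcm3 (2.69 ± 0.44), with a camera adjusted p of 2.06e-09 (adjusted p = 0.267 with an estimated correlation). Of 28 p53 target genes 14 rose and 1 fell (18 and 3 adjusted over the list alone, camera adjusted p = 6.71e-05, adjusted p = 0.184 with an estimated correlation), including Pmaip1, a gene that promotes apoptosis (3.56 ± 0.68), and Cdkn1a, the gene of the cell cycle inhibitor p21 (1.93 ± 0.48), and Trp53 itself was higher (2.5 ± 0.49). Dusp4, a phosphatase gene induced by MAPK signalling (4.21 ± 0.68), the cytokine gene Lif (3.73 ± 0.55) and the metalloproteinase gene Mmp7 (4.69 ± 0.72) also rose, and Insig1, a feedback gene of cholesterol synthesis, fell by 2.38 ± 0.39. Normal libraries moved several of these. Without replicate 2 Mcm3 was at 3.48, Pmaip1 at 2.97 and Mmp7 at 4.09. Without replicate 3 Dusp4 was at 5.4 and Mmp7 at 6.11. Without replicate 4 Pmaip1 was at 4.65 and Cdkn1a at 2.99. Il33, which encodes an alarmin (1.84 ± 0.768 against 0.834 ± 0.429 CPM, adjusted p = 0.362), Cdkn2a, the gene of the tumour suppressors p16 and p19Arf (adjusted p = 0.195), and Sox9, a duct transcription factor gene (adjusted p = 0.424), did not pass.

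By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15145 genes, 3240 genes changed between Injury and Normal, 1833 higher and 1407 lower, of which 1630 and 1144 changed over 2-fold. The balance of directions moved with processing. The calls were 1692 higher and 1636 lower with DESeq2's median-of-ratios factors in edgeR, 1277 and 1308 when only these 2 groups were fitted, and 2260 and 1261 with a correction for transcript length. Of the genes named as changed, Cdkn1a had the highest adjusted p (0.00644). Fibroblast and stellate cell markers were also higher in Injury libraries, with 9 of 20 called and none lower (9 adjusted over the list alone, camera adjusted p = 0.000831, adjusted p = 0.601 with an estimated correlation), and their mean log2 CPM was 3.99 ± 0.713 against 1.95 ± 1.33. Without Normal replicates 1 and 4, which had the fewest detected genes, 1931 genes were called.

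Kras* was set against Normal to describe the mutant allele without injury. Muc6, a gene of the gel-forming mucin of gastric glands (chromosome 7, 141633456 to 141655319), rose from 9.20 ± 4.02 CPM (SD, n = 4) to 1870 ± 83.1 CPM (n = 3), a log2 fold change of 7.62 ± 0.85 (SE). Ctse, the gene of gastric cathepsin E, rose by a log2 fold change of 6.36 ± 0.60, and Onecut2, a transcription factor gene, by 7.17 ± 1.01. Krt7 (5.26 ± 0.54), Krt19 (3.43 ± 0.42) and Sox9 (1.69 ± 0.36) were higher. The acinar regulators Ptf1a (-2.93 ± 0.70) and Bhlha15 (-4.40 ± 0.70) and the lipase gene Pnlip (-10.57 ± 1.49) were lower, and for Muc6, Ctse, Onecut2 and Pnlip the libraries of the groups did not overlap. Of genes that MAPK signalling induces, Plaur (5.41 ± 0.66) and Dusp4 (5.30 ± 0.70) rose, and Areg, the gene of the EGF receptor ligand amphiregulin, had a ratio of 314 with a 95% counting interval of 56.4 to 12400, because the Normal libraries held 1 count. The matrix gene Fn1 (5.89 ± 0.74), Lif (4.90 ± 0.57) and Il33 (3.35 ± 0.77, 9.01 ± 8.95 against 0.834 ± 0.429 CPM) rose as well. Normal replicates 1 to 4 held 1, 4, 1 and 1 counts of Il33, so the size of its changes against Normal is imprecise. Il33 was at 3.85, 19.3 and 3.83 CPM in Kras* replicates 1 to 3. Without replicate 2 its log2 fold change was 2.15 (adjusted p = 0.0226). Of the Kras* libraries it also had the highest mean log2 CPM of fibroblast markers, 5.42 against 3.03 and 2.38. Bhlha15 was at -5.34 without Kras* replicate 2. Without Kras* replicate 3 Ptf1a was at -2.34 and Pnlip at -9.95. Onecut2 was at 8.08 without Normal replicate 2, which held the count of Areg, and Dusp4 at 6.48 without Normal replicate 3.

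All 28 acinar secretory genes fell with mutant Kras alone, also adjusted over the list alone (camera adjusted p = 2.42e-21, adjusted p = 0.218 with an estimated correlation). Of 32 gastric and precursor lesion genes tested 22 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 3.24e-09, adjusted p = 0.226 with an estimated correlation). Of the 24 RAS-MAPK output genes 21 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 1.68e-10, adjusted p = 0.184 with an estimated correlation). Of 22 cholesterol synthesis genes 11 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.00162, adjusted p = 0.472 with an estimated correlation), including Hmgcr, the gene of the rate-limiting enzyme (2.99 ± 0.44, and 3.61 without Normal replicate 2). Of 24 glycolysis and hypoxia genes 11 rose and 1 fell, and 11 and 1 adjusted over the list alone, with the hexokinase gene Hk1 at 3.64 ± 0.43 and the glucose transporter gene Slc2a1 at 2.57 ± 0.45 (camera adjusted p = 0.0112, adjusted p = 0.425 with an estimated correlation). Of the unfolded protein response genes 14 of 22 fell and none rose (14 adjusted over the list alone, camera adjusted p = 2.47e-10, adjusted p = 0.226 with an estimated correlation), led by the amino acid stress genes Chac1 (-4.02 ± 0.59) and Asns (-3.28 ± 0.41). Chgb, the gene of a granin of neuroendocrine cells, rose from 2.06 ± 1.54 to 133 ± 91.6 CPM. Endocrine cell markers did not pass as a list: of 17 tested 4 rose and 2 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.967, adjusted p = 0.992 with an estimated correlation). Fibroblast and stellate cell markers did not pass as a list, with 6 of 20 higher and none lower (9 higher adjusted over the list alone). Their median log2 fold change was 1.63 (camera adjusted p = 0.0913, adjusted p = 0.591 with an estimated correlation). With the replicate number as a block they passed (camera adjusted p = 0.0292). Kras itself was higher (1.45 ± 0.37).

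In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4857 genes changed between Kras* and Normal, 2728 higher and 2129 lower, of which 2510 and 1922 changed over 2-fold. Of the genes named as changed, Kras had the highest adjusted p (0.00471). With a correction for transcript length the calls were 3267 higher and 1621 lower, and without Normal replicates 1 and 4, the libraries with the fewest detected genes, 3088 genes were called and neither Ptf1a (-2.20) nor Kras (1.11) passed. Without Kras* replicate 3 the lower genes numbered 1397.

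Kras*+Injury was set against Normal to describe early neoplasia, in which mutant Kras and injury are combined. Pnlip stood at 14.8 ± 15.0 CPM (SD, n = 4) against 113000 ± 59900 CPM (n = 4) in Normal, a log2 fold change of -12.88 ± 1.41 (SE). Ptf1a fell by 5.00 ± 0.69 to 0.663 ± 0.339 CPM and Bhlha15 by 6.84 ± 0.70. Muc6 (8.00 ± 0.86), Gkn3, a gene of the gastrokine family of the stomach (6.86 ± 0.70), Krt19 (4.73 ± 0.43) and Mmp7 (6.27 ± 0.70) rose. Il33 rose by a log2 fold change of 3.86 ± 0.73 to 12.8 ± 7.43 CPM, Cdkn2a by 3.77 ± 0.78, Hmgcr by 3.39 ± 0.43 and Kras by 1.43 ± 0.35. Normal replicates 1 to 4 held 2, 2, 0 and 1 counts of Cdkn2a, so the size of its changes against Normal is imprecise. Sel1l, which acts in the degradation of misfolded proteins, fell by 4.31 ± 0.45. Without Kras*+Injury replicate 4 Pnlip was at -13.84. Without Normal replicate 2 Hmgcr was at 4.01 and Mmp7 at 5.67, and without Normal replicate 3 Mmp7 was at 7.69.

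All 28 acinar secretory genes were lower, and 26 of 32 gastric and precursor lesion genes were higher with none lower (28 for each list adjusted over the list alone). The camera adjusted p was 2.08e-26 for the acinar list (adjusted p = 0.184 with an estimated correlation) and 3.18e-12 for the gastric list (adjusted p = 0.184 with an estimated correlation). Of 24 ductal and metaplasia genes 21 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 3.12e-11, adjusted p = 0.184 with an estimated correlation). Of 12 acinar transcription factors 8 fell (9 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000265, adjusted p = 0.184 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4695 genes changed, 2833 higher and 1862 lower. Upper-quartile scaling gave 2393 higher and 2302 lower. Of the genes named, Kras had the highest adjusted p (0.00328), and it did not pass without Normal replicates 1 and 4 (1.04). Without Kras*+Injury replicate 4 4204 genes were called.

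**Figure D2:**
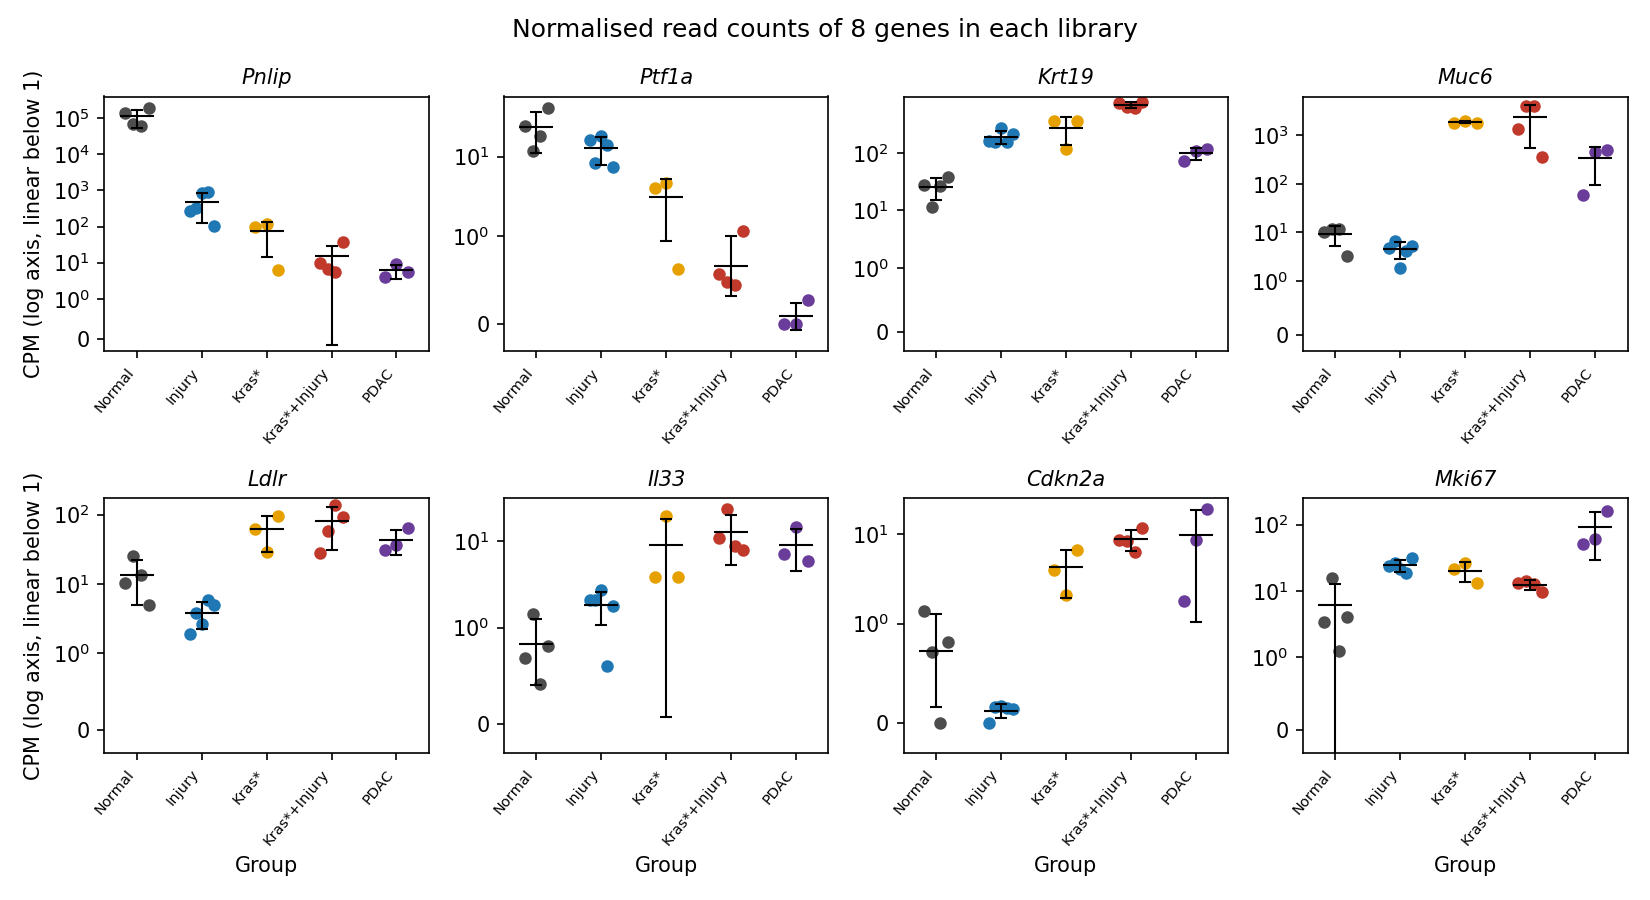
CPM (y axis, logarithmic above 1 and linear below) of 8 genes in each library, by group on the x axis. Points are libraries, and the horizontal line and bar give the group mean and SD, a bar running to the lower edge where the SD exceeds the mean. Pnlip falls from 113000 CPM in Normal to 6.10 CPM in PDAC libraries, and Muc6 lies at 4.58 CPM in Injury and at 1870 CPM in Kras* libraries.

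Kras*+Injury was also set against Kras*, which gives the effect of injury on cells that already carry the mutant allele. Krt19 was at 677 ± 84.5 CPM (SD, n = 4) against 275 ± 139 CPM (n = 3) in Kras*, a log2 fold change of 1.30 ± 0.41 (SE, adjusted p = 0.216). Ptf1a was at 0.663 ± 0.339 against 3.11 ± 2.17 CPM (-2.07 ± 0.67, adjusted p = 0.221). Il33 (0.51 ± 0.52, adjusted p = 0.668), Cdkn2a (1.03 ± 0.54, adjusted p = 0.365) and Mki67, a marker gene of dividing cells (-0.70 ± 0.46, adjusted p = 0.470), did not pass either. Without Kras* replicate 2 Il33 was at 1.73, still not passing. As lists, acinar secretory genes had a median log2 fold change of -1.98 (camera adjusted p = 2.92e-09, adjusted p = 0.405 with an estimated correlation), and 5 of 28 were lower adjusted over the list alone. Gastric and precursor lesion genes had a median of 0.88 (camera adjusted p = 1.01e-05, adjusted p = 0.332 with an estimated correlation), with 8 of 32 higher adjusted over the list alone. Cholesterol synthesis genes (median 0.54, camera adjusted p = 1.06e-05, adjusted p = 0.282 with an estimated correlation) had no member called, while 3 of 24 glycolysis and hypoxia genes were higher adjusted over the list alone (median 0.56, camera adjusted p = 0.000326, adjusted p = 0.248 with an estimated correlation). Immune cell markers were higher (median 0.61, camera adjusted p = 0.0494, adjusted p = 0.752 with an estimated correlation), with none of 17 called, and did not pass without Kras* replicates 1 or 3 or Kras*+Injury replicate 1 (up to 0.974).

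In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15145 genes passed between Kras*+Injury and Kras*, where 2337 had an unadjusted p under 0.05 against 757 expected by chance, and the lowest adjusted p was 0.115. DESeq2 called 255 genes, limma's voom with sample quality weights 1945, and edgeR without the filter on low counts 517. Ptf1a was among the calls of DESeq2 (-2.32) and of edgeR without the filter (-1.95), and Krt19 (1.12) and Il33 (1.35) among those of voom. Without Kras*+Injury replicate 4 there were 3 calls and without Kras* replicate 3 there were 17. Across the 5463 genes with a mean log2 CPM of at least 3, the log2 fold change correlated with transcript length at a Spearman coefficient of -0.71, genes not being independent replicates.

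Kras*+Injury against Injury gives the effect of the mutant allele in injured tissue. Muc6 rose from 4.58 ± 1.77 CPM (SD, n = 5) to 2420 ± 1870 CPM (n = 4), a log2 fold change of 9.06 ± 0.80 (SE). Lgals4, a galectin gene of the gut epithelium (7.13 ± 0.55), Agr2, which encodes a disulfide isomerase needed for mucin production (6.93 ± 0.64, 323 ± 161 against 2.55 ± 2.00 CPM), and Gkn3 (4.80 ± 0.57) also rose, with no overlap between the libraries of the groups. Ptf1a (-4.14 ± 0.64) and Bhlha15 (-4.46 ± 0.62) were lower, and Krt19 was higher (1.83 ± 0.35). Of 2 related homeobox genes of the Onecut family, Onecut2 rose (4 ± 0.68, and 5.16 without Injury replicate 5) and Onecut1 fell (-3.41 ± 0.64). Il33 rose from 1.84 ± 0.768 to 12.8 ± 7.43 CPM (2.77 ± 0.50), as did the neutrophil chemokine gene Cxcl1 (2.34 ± 0.49), while Cxcl12, the gene of the ligand of the receptor CXCR4, fell (-2.09 ± 0.41). Cdkn2a rose from 0.123 ± 0.0696 to 8.85 ± 2.30 CPM, Fn1 by a log2 fold change of 3.49 ± 0.59, and Trp53inp1, a p53 target gene, fell by 1.88 ± 0.36. Injury replicates 1 to 5 held 0, 1, 2, 1 and 1 counts of Cdkn2a, so the size of its rise is imprecise.

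Of 32 gastric and precursor lesion genes 27 rose and none fell, the same counts as adjusted over the list alone (camera adjusted p = 2.14e-19, adjusted p = 0.184 with an estimated correlation). Of 22 cholesterol synthesis genes 21 rose, also adjusted over the list alone (camera adjusted p = 2.6e-18, adjusted p = 0.184 with an estimated correlation), with the low-density lipoprotein receptor gene Ldlr at 4.39 ± 0.50 and Cyp51, a gene of sterol synthesis, at 3.01 ± 0.39. Of 24 RAS-MAPK output genes 20 rose and none fell (22 and 1 adjusted over the list alone, camera adjusted p = 7.42e-12, adjusted p = 0.184 with an estimated correlation), including Areg (5.01 ± 0.53) and Plaur (3.20 ± 0.47). Of 24 glycolysis and hypoxia genes 11 rose and none fell (16 adjusted over the list alone, camera adjusted p = 3.44e-08, adjusted p = 0.184 with an estimated correlation), with Hk2 at 2.55 ± 0.38 and Slc2a1 at 2.09 ± 0.38. Acinar secretory genes fell in 24 of 28 cases (27 adjusted over the list alone, camera adjusted p = 6.13e-19, adjusted p = 0.226 with an estimated correlation). Of 25 interferon response genes 5 fell and none rose (6 adjusted over the list alone, camera adjusted p = 0.00021, adjusted p = 0.282 with an estimated correlation). Endothelial cell markers were lower (median -0.7, camera adjusted p = 0.0333, adjusted p = 0.712 with an estimated correlation), with none of 15 called. They did not pass without Injury replicates 3 or 5 or Kras*+Injury replicates 2 or 3 (up to 0.144), or with the replicate number as a block (0.071).

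By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2140 genes changed between Kras*+Injury and Injury, 1374 higher and 766 lower, of which 1177 and 676 changed over 2-fold. Of the genes named as changed, Cxcl1 had the highest adjusted p (0.00193). With upper-quartile scaling the calls were 1171 higher and 1006 lower. DESeq2 called 1363 lower genes and voom 1497, and limma's voom with sample quality weights called 3362 genes. Without Kras*+Injury replicate 4 1654 genes were called. Kras (0.64 ± 0.30, adjusted p = 0.177) and Trp53 (0.15 ± 0.40, adjusted p = 0.862) did not pass between these groups.

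**Figure D3:**
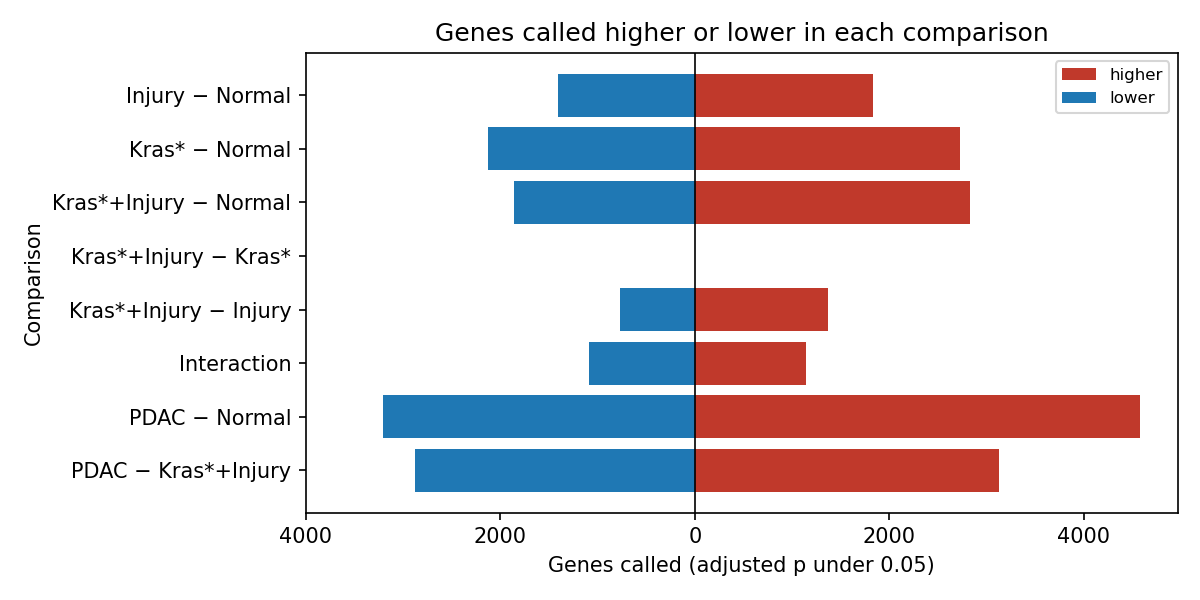
Number of genes (x axis) called higher, to the right of 0, or lower, to the left, at an adjusted p under 0.05 by edgeR's quasi-likelihood test in each comparison (y axis), out of 15145 genes. PDAC against Normal has 4575 higher and 3205 lower genes, and Kras*+Injury against Kras* has 0.

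The interaction of genotype and injury asks whether injury changed a gene by another amount in mutant than in wild-type Kras cells, and a positive value means a more positive change in mutant cells. Tff2 fell with Injury in wild-type cells and was at 265 ± 48.4 CPM (SD, n = 3) in Kras* and 1500 ± 914 CPM (n = 4) in Kras*+Injury, and its interaction was 7.31 ± 0.96 (log2, SE). Genes that rose with Injury in wild-type cells had negative values: Sox4 (-4.37 ± 0.45, with 30.4 ± 4.26 CPM in Kras* and 30.7 ± 1.51 CPM in Kras*+Injury), Sprr1a (-5.14 ± 0.81), Lif (-3.75 ± 0.69) and Serpinb6b, a protease inhibitor gene (-4.40 ± 0.47). Insig1 (2.52 ± 0.58), Asns (2.18 ± 0.49) and Manf, a gene of the endoplasmic reticulum stress response (2.53 ± 0.55), had positive values, as did Pnlip (5.52 ± 1.36, which did not pass without Normal replicates 1 and 4, at 4.65). Pnlip was at 4.46 without Kras*+Injury replicate 4 and at 4.93 without Kras* replicate 3, and Tff2 at 6.71 without Normal replicate 4. Anxa10 and Psrc1, a p53 target gene, also had negative values, whose size is not measured because the Normal libraries held 1 and 2 counts. The fitted values were -5.96 for Anxa10, or -10.48 without Normal replicate 2, and -5.10 for Psrc1, or -10.59 without Normal replicate 3, the libraries with these counts. Psrc1 was at -4.52 without Normal replicate 2. Il33 (-0.59 ± 0.98, adjusted p = 0.709), Ptf1a (-1.21 ± 0.87, adjusted p = 0.345) and Cdkn2a (3.27 ± 1.34, adjusted p = 0.1) did not pass, Cdkn2a passing with DESeq2 (3.30) and with edgeR without the filter on low counts (3.29). Without Kras* replicate 2 Il33 was at 0.63, and without Kras*+Injury replicate 4 Ptf1a was at -1.8, neither passing. Of the unfolded protein response genes 9 of 22 had a positive interaction and none a negative value (12 adjusted over the list alone, camera adjusted p = 6.93e-08, adjusted p = 0.267 with an estimated correlation). Of the proliferation genes 8 of 30 had a negative interaction and none a positive (12 adjusted over the list alone, camera adjusted p = 1.61e-05, adjusted p = 0.435 with an estimated correlation), and of the p53 target genes 9 were negative and 2 positive (10 and 2 adjusted over the list alone, camera adjusted p = 0.00305, adjusted p = 0.226 with an estimated correlation).

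In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2225 genes had an interaction, 1141 positive and 1084 negative. Of the genes named with an interaction in the paragraph before, Pnlip had the highest adjusted p (0.0121). Of the 1084 genes with a negative value, 817 were called higher both in Injury and in Kras* against Normal, and of the 1141 with a positive value 715 were called lower in both. No gene had a called interaction of the sign of both called single changes. The single comparisons shared 2643 calls, of which 2639 went the same way, against 528 for independent lists of these sizes. Both use the same Normal libraries, which raises the sharing. Their fold changes had r = 0.86, against 0.79 in simulated unchanged groups and 0.47 with the Normal libraries divided, and the covariance was 3.64 against a simulated 0.94. By single libraries, 1291 genes passed without Kras* replicate 3, 1387 without Kras* replicate 2 and 1421 without Kras* replicate 1. The positive values among them numbered 557, 608 and 706, and 728 without Kras*+Injury replicate 1. Which sign had more calls also turned with DESeq2, which called 1549 positive and 1770 negative values, and with median-of-ratios factors in edgeR (1101 and 1267). It turned as well with upper-quartile factors (1132 and 1200), no filter (1066 and 1252), voom (1311 and 1352) and the replicate block (698 and 721). The same held with the fibroblast covariate (916 and 938) and without PDAC (1182 and 1278). Positive values stayed more numerous with TMM without acinar secretory genes (1129 and 1117) and with the filter of 5 CPM in 3 libraries (1282 and 1052). Without Normal replicates 1 and 4 there were 704 calls, without Kras* replicate 2 and Kras*+Injury replicate 1 together 845, and with a correction for transcript length 530 positive and 1210 negative, where the Spearman coefficient of the interaction with transcript length was -0.57 across 5463 genes.

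PDAC was set against Normal to describe the carcinoma cells. Pnlip was at 6.10 ± 2.59 CPM (SD, n = 3) against 113000 ± 59900 CPM (n = 4), a log2 fold change of -14.17 ± 1.68 (SE), and the acinar regulators Ptf1a (-8.01 ± 0.94) and Bhlha15 (-8.82 ± 0.88) were lower. Onecut2 rose from 0.943 ± 0.886 to 334 ± 133 CPM, Fn1 by a log2 fold change of 6.54 ± 0.76 and the mesenchymal filament gene Vim by 4.45 ± 0.63. Krt19 rose as well (1.95 ± 0.41, 98.4 ± 22.7 CPM). Mki67 (3.80 ± 0.53), Cdkn2a (3.93 ± 0.79), Il33 (3.38 ± 0.76), Hk1 (4.49 ± 0.43) and Kras (2.80 ± 0.37) were higher. The MAPK-induced genes Etv4 and Areg had 2 counts and 1 count over all Normal libraries, with ratios of 75.5 (95% counting interval 20.9 to 624) and 257 (46.2 to 10200). Asns (-6.07 ± 0.48) and Chac1 (-6.12 ± 0.66) fell, as did the islet hormone genes Ins2 (-10.20 ± 1.14) and Gcg (-7.35 ± 0.89). Without PDAC replicate 1 Vim was at 3.04, Fn1 at 5.37 and Ptf1a at -7.4. Without PDAC replicate 3 Mki67 was at 3.01, Cdkn2a at 2.95 and Ptf1a at -11.83. PDAC replicates 1 to 3 held 0, 0 and 9 counts of Ptf1a. The size of its fall is thus not measured without replicate 3 and rests on that library otherwise. Without Normal replicate 2, which held the count of Areg, Mki67 was at 5.1, Etv4 at 5.53 and Onecut2 at 9.16. Etv4 was at 6.88 without Normal replicate 4.

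All 28 acinar secretory genes were lower in PDAC than in Normal libraries, also adjusted over the list alone (camera adjusted p = 4.43e-25, adjusted p = 0.184 with an estimated correlation). Of 24 RAS-MAPK output genes 23 were higher, also adjusted over the list alone (camera adjusted p = 9.16e-08, adjusted p = 0.226 with an estimated correlation), and of 30 proliferation genes 26, also adjusted over the list alone (camera adjusted p = 2.19e-07, adjusted p = 0.334 with an estimated correlation). Of 22 unfolded protein response genes 20 were lower, also adjusted over the list alone (camera adjusted p = 1.21e-13, adjusted p = 0.184 with an estimated correlation). Of 17 endocrine cell markers tested 10 were lower and none higher, also adjusted over the list alone (camera adjusted p = 4.54e-05, adjusted p = 0.340 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7780 genes changed, 4575 higher and 3205 lower, of which 4224 and 2932 changed over 2-fold, and of the genes named as changed Il33 had the highest adjusted p (0.000938). With a correction for transcript length the calls were 5597 higher and 2404 lower, the Spearman coefficient of the fold change with transcript length being 0.49 across 5463 genes. Without Normal replicates 1 and 4 the higher genes numbered 3001. PDAC and Normal also differ in treatment and in the Trp53 allele, so the comparison joins these differences.

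PDAC against Kras*+Injury sets carcinoma against early neoplasia. Genes of dividing cells were higher in PDAC. Mki67 (chromosome 7, 135689784 to 135716361) rose from 12.4 ± 2.04 CPM (SD, n = 4) to 91.2 ± 62.2 CPM (n = 3), a log2 fold change of 2.88 ± 0.47 (SE), Cenpf, a kinetochore gene, by 2.99 ± 0.39, and Foxm1, a mitotic transcription factor gene, by 2.45 ± 0.46. Mucous and gastric genes were lower, with Tff2 at 13.2 ± 6.50 against 1500 ± 914 CPM (-6.83 ± 0.85), Agr2 at -5.82 ± 0.75 and Gkn3 at -5.26 ± 0.73. Krt19 fell by 2.78 ± 0.43. Reg3b, an antimicrobial lectin gene induced in pancreatitis (-5.54 ± 1.02), Cdkn1a (-2.13 ± 0.53), the p53 target gene Ptp4a3 (-2.38 ± 0.36), Fdps, a gene of the mevalonate pathway (-2.5 ± 0.45), and Ins2 (-7.18 ± 1.05) were also lower. Ank, the gene of a pyrophosphate transporter, was higher (4.85 ± 0.57, 111 ± 138 against 3.88 CPM). Its value was 2.96 without PDAC replicate 1. Mki67 was at 50.7, 60.1 and 163 CPM in PDAC replicates 1 to 3, and its value was 2.06 without replicate 3. Without that library Agr2 was at -6.54, Tff2 at -7.42 and Reg3b at -7.32. Gkn3 was at -6.51 without PDAC replicate 2, Ins2 at -5.98 without Kras*+Injury replicate 1 and Reg3b at -4.93 without Kras*+Injury replicate 4. Il33 (-0.48 ± 0.52, adjusted p = 0.473) and Cdkn2a (0.16 ± 0.52, adjusted p = 0.821) did not pass, Cdkn2a passing after a correction for transcript length. Il33 was at -1.09 without PDAC replicate 2 and Cdkn2a at -0.87 without PDAC replicate 3, neither passing.

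EMT and invasion genes did not pass as a list between PDAC and Kras*+Injury. Of 23 tested, 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.948, adjusted p = 0.992 with an estimated correlation). Single mesenchymal genes that rose rested on PDAC replicate 1: Zeb1 (2.77 ± 0.61) and Zeb2 (2.92 ± 0.78), genes of transcription factors of the epithelial to mesenchymal transition, Vim (2.16 ± 0.56) and the receptor kinase gene Axl (2.60 ± 0.66) passed with all libraries. Without PDAC replicate 1 the values were 1.48 for Zeb1, 1.34 for Zeb2, 0.71 for Vim and 0.99 for Axl, and none passed. Kras (1.37 ± 0.34, adjusted p = 0.00416) did not pass without PDAC replicate 2 (0.75). Of 30 proliferation genes 17 rose and none fell, also adjusted over the list alone (camera adjusted p = 9.5e-05, adjusted p = 0.490 with an estimated correlation). Of 32 gastric and precursor lesion genes 17 fell and 2 rose (17 and 3 adjusted over the list alone, camera adjusted p = 4.79e-07, adjusted p = 0.275 with an estimated correlation), and of 28 p53 target genes 12 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 0.000473, adjusted p = 0.184 with an estimated correlation). Of 17 endocrine cell markers 13 fell (15 adjusted over the list alone, camera adjusted p = 1.67e-06, adjusted p = 0.267 with an estimated correlation), and fibroblast and stellate cell markers fell in 9 of 20 cases, also adjusted over the list alone (camera adjusted p = 0.00123, adjusted p = 0.622 with an estimated correlation).

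In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6005 genes changed between PDAC and Kras*+Injury, 3125 higher and 2880 lower. Which direction had more calls turned with each single PDAC library and with Kras*+Injury replicates 1 and 4. Without Kras*+Injury replicate 4 there were 1912 higher and 2577 lower (4489 in all), without PDAC replicate 2 2039 and 2547, and without PDAC replicate 3 2007 and 2505. Without PDAC replicate 1 there were 2464 and 2836, and without Kras*+Injury replicate 1 2122 and 2666. It also turned when only these 2 groups were fitted (3045 and 3065), with the replicate block (2517 and 2598) and with the fibroblast covariate (2151 and 2241). The same held with the filter of 5 CPM in 3 libraries (2296 and 2349) and without Kras* replicate 2 and Kras*+Injury replicate 1 together (2330 and 2577). Of the genes named as changed, Zeb2 had the highest adjusted p (0.00788). The calls were 3901 higher and 2274 lower with DESeq2's median-of-ratios factors in edgeR, and 3178 higher and 1549 lower with a correction for transcript length, the Spearman coefficient of the fold change with transcript length being 0.70 across 5463 genes.

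**Figure D4:**
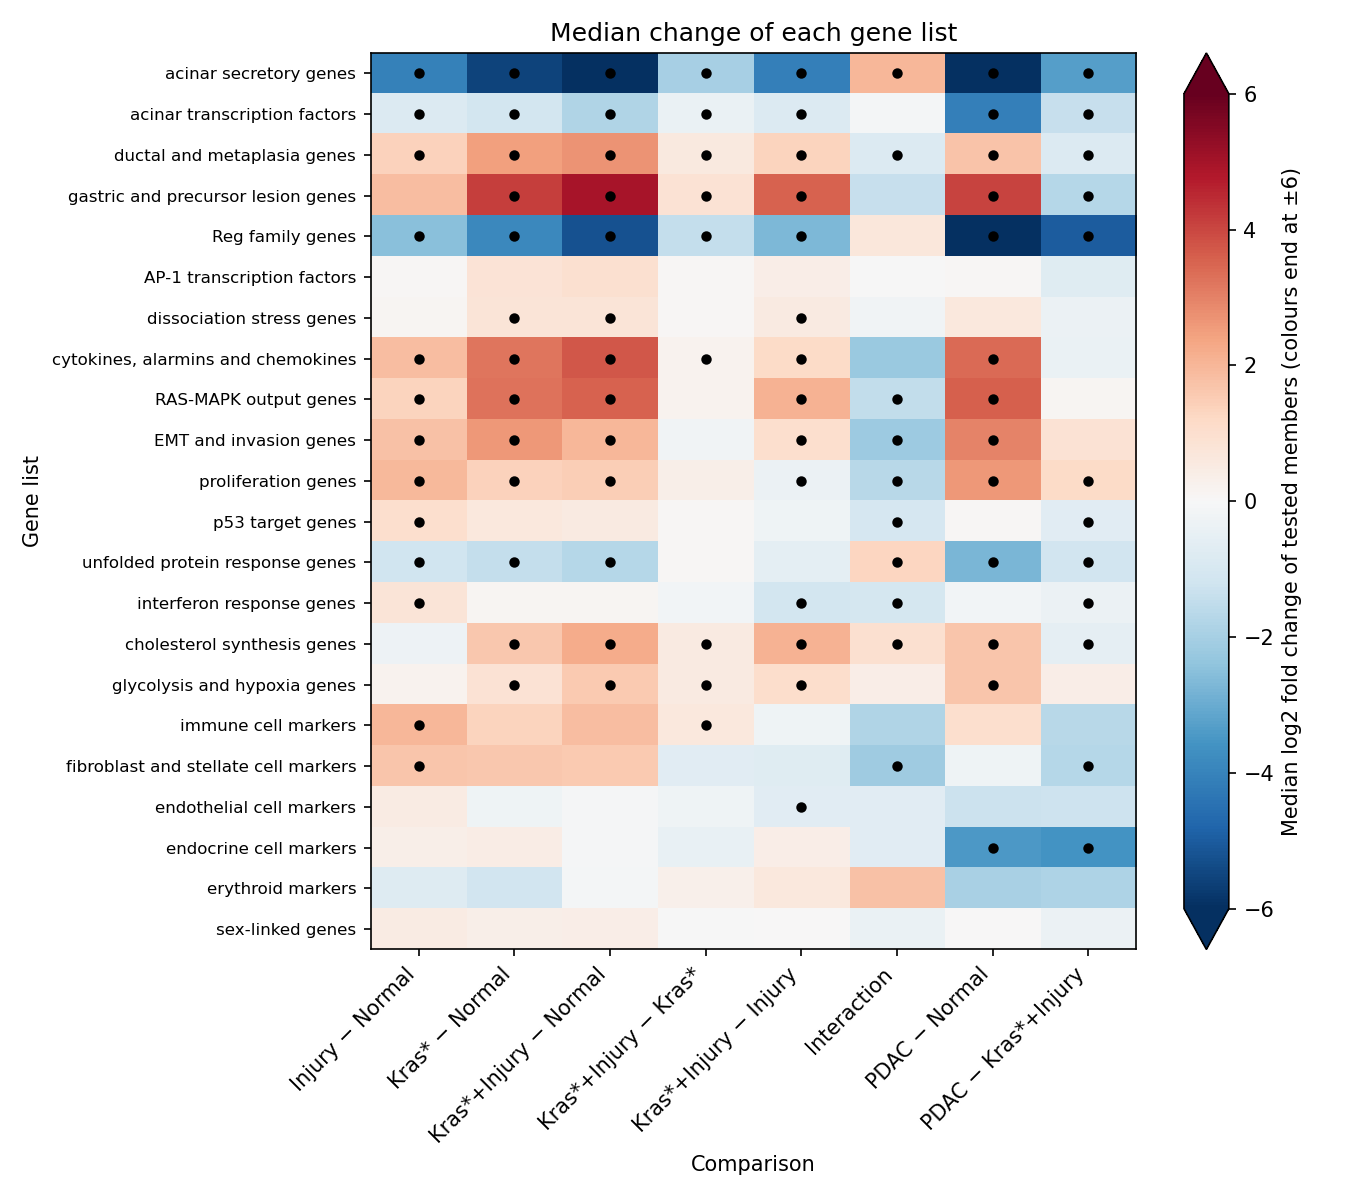
Median log2 fold change (colour, ending at plus and minus 6) of the tested members of each of the 22 gene lists (y axis) in each of the 8 comparisons (x axis), with a dot where camera with its preset correlation gave an adjusted p under 0.05. Acinar secretory genes have a median of -11.26 in PDAC against Normal, and none of the 97 dotted tests passed with an estimated correlation. Fry, not drawn, called 83 of the 176 tests.

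To see how far the carcinoma differences were already present earlier, the log2 fold changes of PDAC against Normal were compared across 15145 genes with those of mutant Kras in injured tissue, Kras*+Injury against Injury, which shares no library with them. Genes such as Onecut2, Fn1, Il33 and Cdkn2a were higher in both comparisons, and Ptf1a and Bhlha15 were lower in both. Pearson's r was 0.37 and Spearman's coefficient 0.20, genes not being independent replicates, where unchanged groups gave a simulated r of 0.02. The covariance was 1.43 against a simulated 0.01, and r lay between 0.29 and 0.43 when libraries were left out 1 at a time, with a jackknife SE of 0.15. With the filter of 5 CPM in 3 libraries r was 0.49. The simulation drew each gene independently, so its spread is too narrow for correlated genes. Both lists called 821 genes higher, against 415 for independent lists, and 484 genes lower, against 162, so that 59.8% of the genes higher with mutant Kras in injured tissue were also higher in PDAC. Genes called in opposite directions numbered 149, against 522 for independent lists.

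The comparisons of Injury, Kras* and Kras*+Injury with Normal share the Normal libraries with that of PDAC, which adds covariance without any effect. For Injury r was 0.78 (Spearman 0.75), against 0.81 in simulated unchanged groups and 0.47 when the Normal libraries were divided between the comparisons, and the covariance was 4.18 against a simulated 0.95. For Kras* r was 0.90, against a simulated 0.80 and 0.61 with divided Normal libraries, and the covariance was 6.04 against 0.95. For Kras*+Injury r was 0.83, against a simulated 0.84 and 0.56 with divided Normal libraries, and the covariance was 5.60 against 0.97. Injury and PDAC shared 1481 higher genes, against 554 for independent lists, and 1258 lower genes, against 298, and the difference between the 3 correlations was not tested.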

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

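The test with divided libraries was set down before its result was seen, its reading against 60% in every division was chosen after, and the tests on transcript length, on the library with another project letter, on fibroblast RNA and on other splits of the libraries were chosen after the results they examine.

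In 213 groups of 4 or 5 libraries, 23 had 1 library whose gap to the nearest of the others was large against the whole range, where chance gives about 1 in 20 groups, here 11. Kras*+Injury replicate 4 stood apart in total counts (gap over range 0.906), in the share of acinar secretory genes (0.943), in counts of all other genes (0.951), in genes detected (0.937), and in Pla2g1b (0.837) and Bhlha15 (0.833). Kras*+Injury replicate 1 stood apart in Sprr1a (0.836), Lif (0.884), Slc2a1 (0.842) and Ins2 (0.867). Among Injury libraries replicate 1 did so in Dusp4 (0.847) and Cdkn2a (0.869), and replicate 4 in Serpinb6b (0.813). Among Normal libraries replicate 1 did so in Hk1 (0.954), Cxcl1 (0.922) and Axl (0.93), and replicate 4 in Muc6 (0.895), Chgb (0.847) and Onecut1 (0.844). The value was 1 for Anxa10, Areg and Cenpf in Normal replicate 2 and for Psrc1 in Normal replicate 3, because the other Normal libraries had equal values.

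The response to injury differed between mutant and wild-type Kras cells, by the interaction in edgeR's quasi-likelihood test, for 30 of the named genes. Positive interactions were found for Tff2 (7.31), Pnlip (5.52), Cela1 (3.96), Agr2 (3.83), Lgals4 (2.57), Manf (2.53), Insig1 (2.52), Ldlr (2.23), Asns (2.18) and Herpud1 (2), in log2 units. Negative interactions were found for Anxa10 (-5.96), Sprr1a (-5.14), Psrc1 (-5.1), Cenpf (-5.04), Serpinb6b (-4.4), Sox4 (-4.37), Dusp4 (-3.84), Lif (-3.75), Mmp7 (-3.51) and Etv4 (-3.16). Smaller negative values belonged to Pmaip1 (-2.96), Ctse (-2.79), Onecut1 (-2.76), Krt7 (-2.73), Mki67 (-2.59), Mcm3 (-2.22), Trp53 (-2.18), Hk1 (-1.74), Trp53inp1 (-1.72) and Krt19 (-1.6). Of the interactions checked in the other settings, which were not all 30, Pnlip, Dusp4 and Agr2 did not pass without Normal replicates 1 and 4. Agr2 did not pass after the transcript length correction, and Dusp4 did not with voom. Without Normal replicates 1 and 4 together, 29.2% of all interaction calls were kept with the same direction. Anxa10, Psrc1, Cenpf and Etv4 rest on 1, 2, 2 and 2 Normal counts, so the size of their values is not measured. Without Normal replicate 2 Anxa10 was at -10.48, Cenpf at -10.51, Psrc1 at -4.52, Mki67 at -3.89, Mcm3 at -3.01, Mmp7 at -2.92 and Pmaip1 at -2.37. Without Normal replicate 3 Psrc1 was at -10.59, Dusp4 at -5.02 and Mmp7 at -4.94. Without Normal replicate 4 Tff2 was at 6.71, Pmaip1 at -4.05 and Etv4 at -3.92. Pnlip was at 4.93 without Kras* replicate 3 and at 4.46 without Kras*+Injury replicate 4.

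Of these 30 interactions, 20 passed without each library in turn and 10 did not. Krt19 kept its call only without Normal replicate 4, Injury replicate 4 or Kras* replicate 2 (adjusted p up to 0.123). Onecut1 kept its call only without Normal replicate 2 or Injury replicates 3 or 4 (up to 0.117). Cela1 kept its call only without Normal replicates 2 or 3, Injury replicates 3 or 4 or Kras*+Injury replicate 3 (up to 0.113), and was at 4.57 and 3.38 without Kras* replicates 2 and 3. Ldlr kept its call only without Normal replicate 4, Injury replicate 4, Kras* replicate 3 or Kras*+Injury replicates 1 or 2 (up to 0.104). Trp53 lost its call without Normal replicates 1 or 2, Injury replicate 5, Kras* replicates 1 or 3 or Kras*+Injury replicates 2 or 4 (up to 0.069). Lgals4 lost it without Normal replicates 3 (1.95) or 4, Injury replicate 1, Kras* replicate 2 or Kras*+Injury replicates 1 or 2 (up to 0.154). Hk1 lost it without Normal replicate 1, Injury replicate 5, Kras* replicates 1 or 3 or Kras*+Injury replicates 1 or 2 (up to 0.0752). Trp53inp1 lost it without Normal replicates 1 or 3, Injury replicates 2 or 5, Kras* replicate 1 or Kras*+Injury replicate 1 (up to 0.0841). Etv4 lost it without Normal replicates 1 or 2 (-2.56) or Kras* replicates 1 or 3 (up to 0.0674), and Pmaip1 without Normal replicate 3 or Kras* replicates 1 or 3 (up to 0.0654).

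Camera with its preset correlation gave an interaction for 10 lists. Positive were unfolded protein response genes (adjusted p = 6.93e-08, adjusted p = 0.267 with an estimated correlation), acinar secretory genes (0.000714, adjusted p = 0.685 with an estimated correlation) and cholesterol synthesis genes (0.000775, adjusted p = 0.435 with an estimated correlation). Negative were proliferation genes (1.61e-05, adjusted p = 0.435 with an estimated correlation), ductal and metaplasia genes (0.00292, adjusted p = 0.472 with an estimated correlation), p53 target genes (0.00305, adjusted p = 0.226 with an estimated correlation) and RAS-MAPK output genes (0.00578, adjusted p = 0.495 with an estimated correlation). Fibroblast and stellate cell markers (0.0148, adjusted p = 0.752 with an estimated correlation), interferon response genes (0.0257, adjusted p = 0.523 with an estimated correlation) and EMT and invasion genes (0.0333, adjusted p = 0.545 with an estimated correlation) were also negative. The fibroblast markers did not pass without Normal replicate 1, Kras* replicate 2 or Kras*+Injury replicate 3 (up to 0.272), the interferon genes without Kras* replicate 2 (0.134), and the EMT genes without Normal replicates 2 or 3, Injury replicate 5, Kras* replicate 2 or Kras*+Injury replicate 3 (up to 0.102).

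Genes such as Sox4 and Lif that rose both with Injury and with Kras* had a negative interaction, and 1532 of 2225 genes with an interaction had changed the same way in both single comparisons. Libraries shared by the single comparisons and the interaction could produce this, and with the libraries divided so that none was shared, 91.6% of genes changed the same way still had an interaction of the opposite sign, averaged over 180 divisions, against 53% negative among all genes. If chance values of the shared libraries were the whole cause, 60% or fewer would be expected. The lowest division gave 73%, which argues against such values as the whole cause. A difference common to all Normal libraries enters the single comparisons and the interaction in every division, so the test cannot address it. The median interaction in these divisions averaged -1.33 for genes higher in both (nearest to 0, -0.39) and 1.45 for genes lower in both (0.65). The stricter bound set beforehand, over 75% in every division, was met in 179 divisions and missed in 1. The divisions share mice with each other and are not independent. Still open are a transcript length trend, whose correction kept 52.2% of the interaction calls with the same direction, and Kras*+Injury replicate 4, without which 73% were kept. That value does not single this library out, since 62.9%, 59.9% and 56% were kept without Kras* replicates 1, 2 and 3, 67% and 67.2% without Normal replicates 1 and 4, and 69% without Kras*+Injury replicate 1. A difference common to all Normal libraries is also open, and 29.2% were kept without Normal replicates 1 and 4 together. A biological explanation, that injury and mutant Kras each bring the cells to a like state, was not tested.

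No gene was called between Kras*+Injury and Kras* by edgeR's quasi-likelihood test, with 2337 at an unadjusted p under 0.05, 255 calls by DESeq2 and 1945 by voom. If Kras*+Injury replicate 4, the library with another project letter, hid the changes, many calls would be expected without it. Without it 3 genes were called, and 36 (8 higher and 28 lower) when the PDAC group was left out as well, which argues against it as the whole cause, although a group of 3 also has less power than a group of 4. Fibroblast RNA differing between libraries could also hide changes. With the fibroblast marker level as a covariate 0 genes were called, and 2315 instead of 2337 had an unadjusted p under 0.05. The covariate brought out no calls, but the test finds few 2-fold changes here, as given below, so this count cannot decide. For the transcript length trend the count cannot decide either. The fold change of this comparison follows length (Spearman coefficient -0.71), so the correction can itself remove differences between the groups. After it 0 genes were called, and 1652 instead of 2337 had an unadjusted p under 0.05. In simulated data the test called 5.97% of genes changed 2-fold in this comparison, so a count of 0 says little about changes of that size. That few changes are added by injury once Kras is mutant remains possible and untested.

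Other splits of the same libraries into groups of the same sizes were fitted for each comparison. In the following comparisons only 1 split, the real one, called as many genes. With 100 of 126 splits drawn these were Injury against Normal (3240, highest other 1941) and Kras*+Injury against Injury (2140, highest other 882). With 35 splits they were Kras* against Normal (4857, highest other 3774) and Kras*+Injury against Normal (4695, highest other 3). PDAC against Normal (7780, highest other 5719) and PDAC against Kras*+Injury (6005, highest other 1443) also had 35 splits. This argues against chance but cannot exclude it, since among 35 splits the real one can be no rarer than 1 in 35. For the interaction 3 of 100 splits drawn from 4410 called as many genes as the real one (2225, highest other 3395), so other splits also gave large counts. These splits exchanged Normal with Kras* libraries and Injury with Kras*+Injury libraries, so a change by mutant Kras alone can enter their counts. The highest other exchanged Injury replicates 1 and 3 with Kras*+Injury replicates 2 and 3 and left Normal and Kras* whole. The splits therefore do not show how many interaction calls chance alone would give. For Kras*+Injury against Kras* the real count is 0, so all 35 splits give as many whatever the data (highest other 21), and the comparison of splits says nothing. The highest others of Kras* and of PDAC against Normal placed Normal replicate 2 with the other group and left the rest of the real split as it is.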

How the results depend on the processing

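The totals, transcript length, fibroblast, 5 CPM and paired leave-out settings were chosen after seeing the data. Across 148 named gene changes and 3578 alternative values, 3551 stayed on their side of the threshold, 14 lost their call and 13 gained one. The 148 do not hold all of the 30 unexpected interactions, whose single-library values stand with them. Where either fit passed, 0 values reversed direction. Changes that passed in neither fit could turn, as the Il33 interaction did from -0.59 to 0.63 without Kras* replicate 2. Of 97 list calls, 80 held without each library in turn, 94 with the replicate block, 97 with TMM without acinar secretory genes, and 0 with an estimated inter-gene correlation. With fry, 83 of all 176 list tests had an adjusted p under 0.05. Counts beyond 1.5 times the values of all libraries were, for Kras*+Injury against Kras* (0), 517 without a filter, 255 with DESeq2, 1945 with voom and sample weights, 3 with the replicate block, 36 without Kras*+Injury replicate 4 and PDAC, and 0 to 17 with libraries left out 1 at a time (17 without Kras* replicate 3, 3 without Kras*+Injury replicate 4). For Kras*+Injury against Injury (2140) voom gave 3362. For the interaction (2225) the block gave 1419, leaving out Normal replicates 1 and 4 gave 704, Kras* replicate 2 with Kras*+Injury replicate 1 gave 845, and single libraries 1291 to 2976 (1421, 1387 and 1291 without Kras* replicates 1, 2 and 3). Without Normal replicates 1 and 4 Injury against Normal had 1931 (3240 with all) and Kras* against Normal 3088 (4857 with all). The cause was not tested. Other totals stayed within 1.5 times, and where only a count by direction went beyond it the value is in the report. The stricter planned filter kept the same 15145 genes and so tested nothing. As for the block, of 33 same-numbered pairs of libraries 11 correlated over 0.1 (-0.25 to 0.27). Pairs with different numbers were not set beside them, so this does not settle whether the numbers pair the mice. Depth limits Normal most, with a floor of 2.4 CPM for 3 counts in replicate 4.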

Other observations

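The test on mast cell RNA was chosen after the values of Mcpt1 and Mcpt2 were seen, and the other values here answer no test of an explanation.

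Mcpt1 and Mcpt2, genes of mast cell proteases (chromosome 14), were chosen after their values were seen. Mcpt2 was at 0.816 ± 0.589 CPM (SD, n = 4) in Normal, 0.137 ± 0.154 (n = 5) in Injury, 21.3 ± 9 (n = 3) in Kras*, 116 ± 56 (n = 4) in Kras*+Injury and 7.48 ± 3.13 CPM (n = 3) in PDAC libraries. Mcpt1 was at 0.103 ± 0.205, 0, 11.1 ± 3.19, 52.6 ± 24.2 and 2.58 ± 0.746 CPM in the same groups. Mast cells could bring this RNA, though the sort removed CD45-positive cells. The abundant mast cell transcripts Cpa3 and Tpsb2 reached at most 0.137% of the Mcpt2 counts in any Kras*+Injury library. This argues against mast cells that express these genes. Of other mast cell genes, Ms4a2 and Fcer1a had 0 counts in Kras*+Injury libraries, while Mcpt4 was at 1.27 ± 0.467 CPM. Kit was at 15.9 ± 4.4 CPM there and at 16 ± 4.52 CPM in Normal. Mcpt1 and Mcpt2 are paralogs that can share reads, so the level of each alone is uncertain, and expression in the epithelial cells was not tested otherwise.

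Lists without a place in the comparisons had the following values. Reg family genes, of pancreatic stress lectins, fell in all 6 tested cases in PDAC against Normal (median log2 fold change -9.77, camera adjusted p = 2.48e-07, adjusted p = 0.213 with an estimated correlation) and in 3 of 6 in Injury (4 adjusted over the list alone, median -2.5, camera adjusted p = 0.00331, adjusted p = 0.433 with an estimated correlation). Cytokines, alarmins and chemokines rose in 17 of 27 cases with Kras* (20 adjusted over the list alone, camera adjusted p = 0.000213, adjusted p = 0.184 with an estimated correlation). EMT and invasion genes rose in 16 of 23 cases in PDAC against Normal, also adjusted over the list alone (camera adjusted p = 0.00169, adjusted p = 0.371 with an estimated correlation). Dissociation stress genes, which respond to tissue digestion, rose in 8 of 20 cases in Kras*+Injury against Injury, also adjusted over the list alone (camera adjusted p = 0.000831, adjusted p = 0.296 with an estimated correlation), and did not pass in Injury against Normal (adjusted p = 0.866). They also rose in Kras* against Normal (9 of 20 higher and 3 lower, also adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.495 with an estimated correlation), but not without Normal replicate 2 (0.085). In Kras*+Injury against Normal 9 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0395, adjusted p = 0.523 with an estimated correlation), but they did not pass without Normal replicate 2 or without Kras*+Injury replicates 2, 3 or 4 (up to 0.0911). AP-1 transcription factors passed in no contrast of the main fit (camera adjusted p = 0.784 in Injury against Normal and 0.115 in Kras*+Injury against Injury). In Kras*+Injury against Injury they passed with the replicate block (0.0402) and in 2 of 9 fits without 1 library. Such fits also passed in 1 of 8 for Kras*+Injury against Normal and 1 of 7 for PDAC against Kras*+Injury. Immune cell markers passed in Injury against Normal (4 of 17 higher, 7 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.645 with an estimated correlation), but not without Injury replicate 3 (0.0569). Endothelial (adjusted p = 0.476), erythroid (0.511) and sex-linked genes (0.639) did not pass there.

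The median, mean and test of a list differed in sign in 18 of 176 tests, none of them called. These were endocrine cell markers for Injury, Kras* and Kras*+Injury against Normal and for Kras*+Injury against Injury, interferon response genes for Kras*+Injury against Normal, and EMT, unfolded protein response, fibroblast, endothelial and sex-linked genes for Kras*+Injury against Kras*. The rest were erythroid and sex-linked genes for Kras*+Injury against Injury, acinar transcription factors and endothelial markers for the interaction, and AP-1, p53 target, immune and sex-linked genes for PDAC against Normal.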
